A study of Gallus gallus with 2 samples.

How the data were processed

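Cells were dissociated from the yolk sac membrane of wild-type, untreated chicken embryos at E4 and E7, captured on the BD Rhapsody system and sequenced on an Illumina NovaSeq X, per the labels' protocols. Both libraries carry the same batch label, and each stage has 1 library, so stage and library cannot be separated. The deposited matrices hold raw counts of molecules per gene and cell, and the authors filtered cells on gene counts and depth, per the series' design text, with thresholds not given in the sources used here. The aligner and counter are not given in the sources used here. The submitters' processing notes name the build GRCg6a. Of 27638 features, 8116 carry a symbol and 19522 only an identifier, and the build of those identifiers was not settled here, so no coordinates are given. Features without a symbol took 26.7% of the UMIs at E4 and 28.2% at E7 and entered totals but no gene list. The deposited per-cell totals equalled the sums of the matrix in 9037 and 6884 cells, which is every cell.

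UMIs per cell ranged from 4651 to 21993 at E4 and from 2998 to 21996 at E7. A count of 0 allows up to 3 counts, which is 0.666 CPM in the E4 and 0.0444 CPM in the E7 endodermal class, summed from 4504587 and 67590004 UMIs. All deposited cells were kept. Scrublet in scanpy called 3 of 9037 cells at E4 and 0 of 6884 at E7 as doublets, too few for the calls to be used, so no doublets were removed and any in the files count in all values. The sources used here do not say whether doublets were removed before deposit. Leaving out the 5% of cells with the highest scores was added as an alternative.

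The deposited cluster numbers were used as the cell annotation, a choice fixed before the data were examined, as were the gene lists, cell type markers, size rules and the rule for named genes. The authors gave the clusters no names, and how they were made is not given in the sources used here, so it is open whether list genes shaped them. Counts were summed per cluster and library with at least 20 cells. A marker counted as raised at 20 CPM or more, 3 times its median over all sums and 10% of its highest sum. The class with the most raised markers, at least 3 and without a tie, named the cluster, unless another class had more markers among the 10 leading genes or the median UMI count was under 33.3% of the library's with none of the class's markers among them, a condition that no deposited cluster met. This form of the rule and the further exclusion of clusters with at least 2 genes of heart muscle, neural, pharyngeal or nephric tissue among their 10 leading symbols were set after the data were seen. The exclusion changed the name of clusters 12 and 16 only. The first form of the rule, by share of markers raised, is kept as an alternative. Markers of mesothelial, smooth muscle, thrombocyte, granulocyte, blood progenitor, germ cell and lymphoid cells named no cluster. Symbols were matched by name, letter case or older names in a RefSeq table of GRCg7b, used for names only, which placed 416 of 617 list entries and 102 of 147 marker entries.

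Own clusterings scaled each cell to 10000 counts, took 2000 variable genes without the list genes and 61 ribosomal protein genes, 30 principal components and 15 exact neighbours, and used Leiden at resolution 1 with seed 1. They gave 26 joint clusters, of which 23 had at least 90% of their cells from 1 library. Sub-clusters of the class used resolution 0.5 and a minimum of 50 cells. The alternatives at other resolutions replace the deposited clusters as well as the resolution, so they differ from the reported shares by both choices.

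For each gene, CPM of the summed counts were compared as a log2 ratio of E7 over E4 with 1 CPM added to each. Shares have exact Clopper-Pearson intervals, levels exact Poisson intervals, and ratios exact conditional binomial intervals, all at 95%. List members were measured at 10 CPM or more in either stage and counted as at least 1.5-fold higher, lower or between. A list median has a counting interval from 1000 Poisson draws and a percentile among 10000 random lists drawn from 20 bins of mean expression. Named genes are the 12 with the largest ratio in each direction (5 in the mesenchymal-like class) among genes with a symbol, 50 CPM and 50 UMIs in the higher stage and an interval that excludes 1.5-fold, without ribosomal protein and globin genes. In each list the up to 4 members with the largest ratios among those at 50 CPM or more and the 2 most abundant members are named, and the lipoprotein lists in full. Not every gene that meets these rules is named in the text. No p-value was computed, since cells are not replicates.

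The ratio rule was tested on simulated counts for the endodermal comparison over 27638 features. It passed 0 of 67 genes set at 1.2-fold, 67 of 67 at 2-fold, 66 of 66 at 4-fold and 0 of 7916 unchanged genes, and 95.1% of 2844 true folds lay inside their interval. The counts were Poisson draws from the pooled profile of the class, without variation between embryos, libraries or cell mixtures. The check therefore covers counting error only and does not show how often the rule passes genes for such reasons. Alternatives covered scaling by edgeR's TMM factors (1.06 at E4, 0.947 at E7), totals without ribosomal and globin genes, per-cell means, the pseudocount, filters, fold bounds and other clusterings. Cells were also thinned to 3800 UMIs each, and free RNA was subtracted as the profile of the other cells of a library, scaled to remove the median globin level. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.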

Results

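Gene expression was measured in single cells of the yolk sac membrane of chicken embryos, the extra-embryonic tissue that takes up yolk, on days 4 (E4) and 7 (E7) of incubation. The series title is about how the endodermal epithelium of this membrane transports lipoproteins. Here, RNA levels of cells named endodermal epithelial-like were compared between the stages. RNA levels do not measure transport, and whether all of these cells at E4 come from the membrane stays open. Each stage had 1 library, so no difference between stages has a replicate check and no test was made. The E4 library held 9037 cells and 114802792 unique molecular identifiers (UMIs), with a median of 12310 UMIs and 4098 detected genes per cell. The E7 library held 6884 cells and 70648070 UMIs, with medians of 9054 UMIs and 3399.5 genes. All intervals are 95% intervals that cover counting error only, and levels are CPM of the counts summed over a class or cluster.

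The share of cells per class shows how the composition of the cell suspension differed between the stages. Endodermal epithelial-like cells were 393 of 9037 cells, 4.35% (3.94% to 4.79%), at E4 and 6558 of 6884 cells, 95.3% (94.7% to 95.8%), at E7. Mesenchymal-like cells were 4902 of 9037 cells, 54.2% (53.2% to 55.3%), at E4 and 165 of 6884 cells, 2.40% (2.05% to 2.79%), at E7. Ectodermal epithelial-like cells, with the keratin genes KRT5 and KRT14, took 4.88% at E4 and 0.407% at E7. Endothelial-like cells took 8.01% and macrophage-like cells 0.996% at E4. Neither class was named at E7, where their clusters 6 and 15 held 3 and 10 cells, under the minimum of 20.

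The endodermal epithelial-like class was made of the deposited clusters 2 (246 cells, 2.72%) and 5 (147 cells, 1.63%) at E4. At E7 it was made of clusters 1 (1627 cells, 23.6%), 2 (1648 cells, 23.9%), 3 (1478 cells, 21.5%), 5 (1327 cells, 19.3%) and 10 (478 cells, 6.94%). The E4 cells of clusters 1 (292 cells, 3.23%), 3 (95 cells, 1.05%) and 10 (123 cells, 1.36%) stayed unnamed. Erythroid-like cells, red blood cell precursors with globin genes, were 99 of 6884 cells, 1.44% (1.17% to 1.75%), at E7, all of cluster 9. The E4 part of cluster 9 (536 cells, 5.93%) was unnamed although HBZ, an embryonic globin gene, stood at 8108 CPM in it. In it 7 of 8 endothelial markers, among them CDH5 and KDR, and 4 of 7 erythroid markers were raised. What these cells are stays open, and the count of 0 erythroid-like cells at E4 depends on the naming rule. Clusters 8, 12, 14 and 16, whose leading genes are known from neural tissue, heart muscle, pharyngeal tissue and the nephric duct, belonged to no class. The naming rule left clusters 8 and 14 unnamed, and an exclusion set after the data were seen did so for clusters 12 and 16. Without it, endodermal epithelial-like cells were 5.27% and mesenchymal-like cells 59.2% at E4. Clusters 8, 12, 14 and 16 held 1441 cells at E4, 15.9% (15.2% to 16.7%), and 1 cell at E7, 0.0145%. The fewest detected genes in a deposited cell were 2501 at E4 and 1501 at E7, and dissociation can set shares. When only cells with more than 2500 genes were kept, which leaves out no E4 cell, the endodermal epithelial-like share at E7 was 96.1%. In a joint clustering made without the deposited numbers, the endodermal epithelial-like shares were 1.66% at E4 and 87.2% at E7, and with list genes allowed for that clustering 2.003% and 89.7%. The first form of the naming rule put clusters 1, 3, 5 and 10 with the erythroid-like cells at E7, which left endodermal epithelial-like cells at 23.9% at E7. At E4 it left only cluster 2, 2.72%, since the E4 cells of cluster 5 lost the name.

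**Figure D1:**
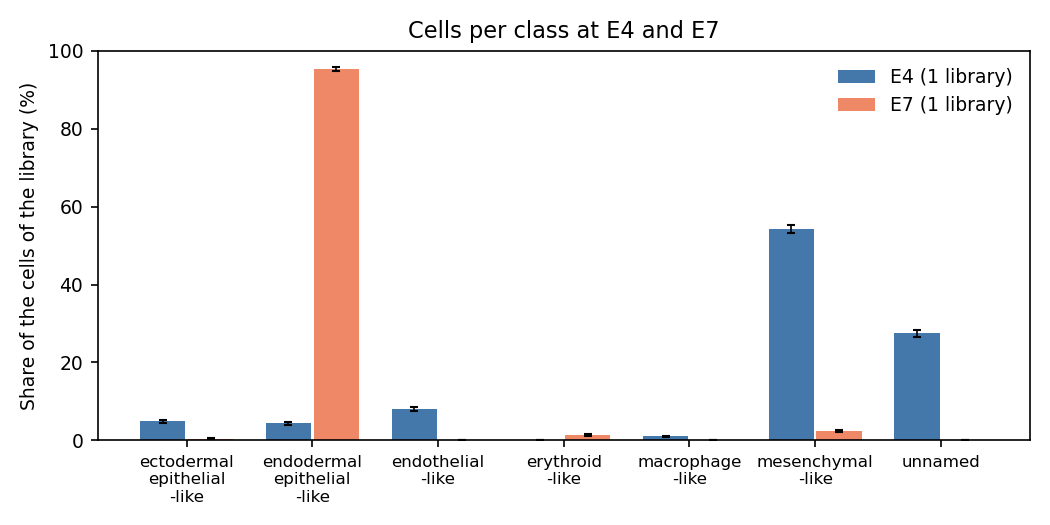
Share of the cells of a library (%) in each class, as bars for E4 and E7 with exact binomial 95% intervals, 1 library per stage. Endodermal epithelial-like cells took 4.35% at E4 and 95.3% at E7.

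Several apolipoprotein genes were higher at E7 in the endodermal epithelial-like cells, while the genes of the assembly list went both ways. APOC3, a small apolipoprotein, was 6.19-fold higher at E7 (18.6 against 115 CPM, interval of the ratio 4.99 to 7.76). APOA1, the main protein of high-density lipoprotein, was 3.97-fold higher at E7 (398 against 1577 CPM, interval of the ratio 3.79 to 4.16). LCAT, which esterifies cholesterol on lipoproteins, was 3.82-fold higher at E7 (7.99 against 30.5 CPM, interval of the ratio 2.75 to 5.47), and APOB, the core protein of very-low-density lipoprotein, was 1.97-fold higher at E7 (23.3 against 45.9 CPM, interval of the ratio 1.62 to 2.42). Over the list of lipoprotein assembly genes, 5 of 13 measured members were at least 1.5-fold higher at E7, 1 at least 1.5-fold lower and 7 between. The median log2 ratio was 0.36 (0.27 to 0.49), at percentile 98.8 of 10000 random lists matched on expression, with 0.55 in cluster 2 and 0.70 in cluster 5.

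With 1 CPM added to each level, as in all counts of list members, the other measured assembly genes included 1 member past the bound in each direction. SAR1B and SAR1A, which encode vesicle coat GTPases, were at 86.8 and 138 CPM and at 51.7 and 35.6 CPM, at E4 and E7 in turn. ABCA1, a cholesterol exporter, was at 6.44 and 10.1 CPM, SEC24C at 123 and 158 CPM, SEC23A at 72.1 and 91.3 CPM, SURF4 at 147 and 169 CPM, MIA3 at 95.9 and 97.0 CPM and P4HB at 473 and 445 CPM. APOH was 2.20-fold higher at E4, at 17.1 and 7.75 CPM, and turned to 1.83 on the log2 scale in a clustering of the cells made without the deposited numbers.

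The apolipoprotein genes were uneven between clusters at E7. APOA1 stood at 5102 CPM in cluster 2, 1289 in cluster 10 and 909 in cluster 5, against 319 in cluster 1 and 346 in cluster 3. Cells of other classes at E7 held 314 CPM (mesenchymal-like), 398 (erythroid-like) and 411 (ectodermal epithelial-like), so the APOA1 levels of clusters 1 and 3 lay within the range of these classes. Whether these levels are free RNA or the cells' own expression was not tested. APOB stood at 168 CPM in cluster 2 and 16.9 in cluster 5 at E7, with 3.30 in cluster 1 and 6.28 in erythroid-like cells. At E4, APOB was at 33.5 CPM in cluster 2 and 0.715 in cluster 5, the latter from 1 count, and APOA1 was at 537 and 87.9 CPM, against 50.3 CPM in E4 mesenchymal-like cells.

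**Figure D2:**
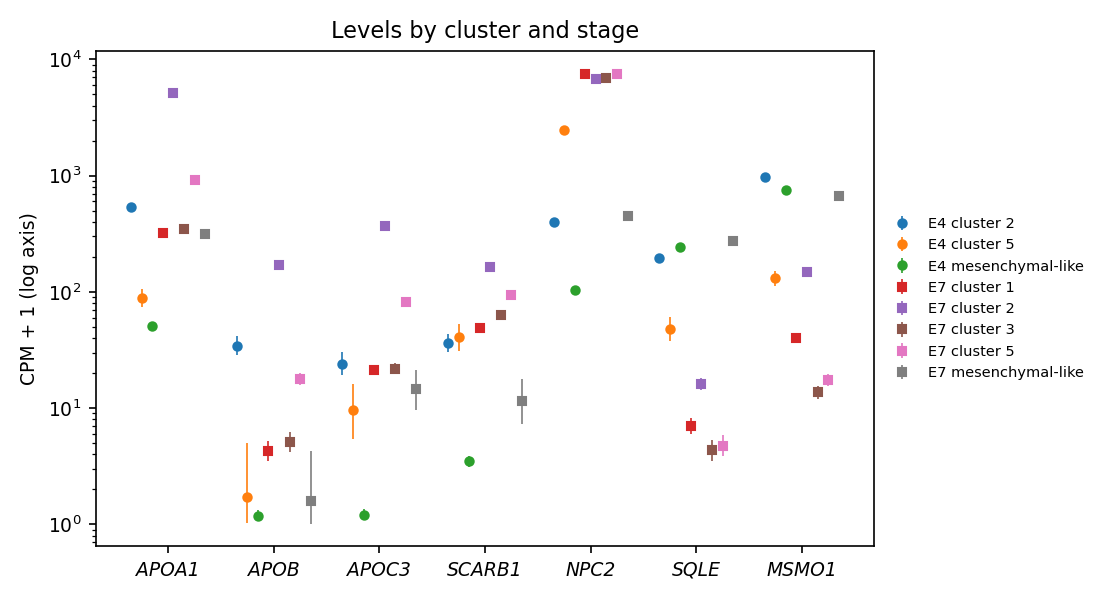
Level of 7 genes in clusters and classes at each stage, as CPM plus 1 on a log axis with exact Poisson 95% intervals; circles are E4 and squares E7, with 1 library each. APOA1 reached 5102 CPM in E7 cluster 2 against 314 in E7 mesenchymal-like cells, and SQLE lay at 196 CPM in E4 cluster 2 and 15.2 in E7 cluster 2.

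Most measured genes of the lipoprotein receptor list were also higher at E7, though few members of the list had a feature. SORL1, a sorting receptor, was 2.40-fold higher at E7 (17.5 against 42.0 CPM, interval of the ratio 1.92 to 3.04). SCARB1, the receptor for high-density lipoprotein, was 2.40-fold higher at E7 (36.9 against 88.3 CPM, interval of the ratio 2.05 to 2.81). VLDLR, the very-low-density lipoprotein receptor, was 2.32-fold higher at E7 (5.55 against 12.9 CPM, interval of the ratio 1.56 to 3.60), and LRPAP1, a chaperone of that receptor family, was 1.76-fold higher at E7 (141 against 248 CPM, interval of the ratio 1.62 to 1.91). MYLIP, a ligase that degrades lipoprotein receptors, was 2.12-fold higher at E4, and SCARB2 was at 13.3 and 19.1 CPM. Of the list, 4 of 6 measured members were at least 1.5-fold higher at E7, 1 at least 1.5-fold lower and 1 between, with a median of 0.95 (0.72 to 1.07), percentile 99.7, and 1.19 in cluster 2 and 0.65 in cluster 5. The median of lipoprotein receptors was lower, at 0.43 in a joint clustering made without the deposited numbers, 0.48 with each library clustered alone and 0.49 without a CPM minimum. SORL1 turned to -0.41 in that joint clustering. LRP2, CUBN, LRP1 and DAB2 were not analysed here, since no feature carried their symbols.

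These class ratios set partly different cells side by side. At E7 the class includes clusters 1, 3 and 10, whose E4 cells stayed unnamed and are not in the E4 sums. Endodermal markers were not the most raised in these E4 cells. In cluster 10 at E4, 10 of 11 mesenchymal markers were raised. In cluster 1 at E4, 3 of 9 ectodermal epithelial and 3 of 5 mesothelial markers were raised. In cluster 3 at E4, 2 of 9 ectodermal epithelial and 2 of 11 mesenchymal markers were. The leading symbols of cluster 2 at E4 were GCG, CYP2C23a, VIPR2, GUCA2B, VSIG1, SPP1, BCAS1, FGG, FGB and LYG2. Of the 246 E4 cells of cluster 2, 205 fell into a single cluster with 213 of the 217 cells of cluster 14, the pharyngeal-led cluster, when all cells were clustered anew. Whether they are cells of the membrane or of the embryo was not settled. The 147 E4 cells of cluster 5 did not hold together in that clustering and spread over 12 clusters, with at most 57 (38.8%) in 1 of them. GATA5, an endodermal transcription factor named here after its values were seen, stood at 58.0 CPM in E4 cluster 2, 16.4 in E4 cluster 5 and 0.196 in E7 cluster 2.

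Genes of cholesterol synthesis were lower at E7 in the endodermal epithelial-like cells. SQLE, which oxidises squalene, was 21.1-fold higher at E4 (149.8 against 7.12 CPM, interval of the ratio 18.7 to 23.7). MSMO1, a sterol demethylation enzyme, was 13.7-fold higher at E4 (713 against 52.0 CPM, interval of the ratio 13.1 to 14.4), HSD17B7 was 12.7-fold and HMGCS1, an early enzyme of the mevalonate pathway, 7.62-fold higher at E4. CYP51A1 was at 292 and 233 CPM. Of the list, 0 of 18 measured members were at least 1.5-fold higher at E7, 13 at least 1.5-fold lower and 5 between, and its median was -2.23 (-2.37 to -2.13), percentile 0. The medians were -2.06 in cluster 2 and -1.02 in cluster 5, and -0.23 in the mesenchymal-like cells (-0.20 in their cluster 4 alone), where SQLE stood at 241 and 271 CPM.

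Fatty acid genes went both ways. FADS2, a desaturase of polyunsaturated fatty acids, was 39.9-fold higher at E4 (77.9 against 1.95 CPM, interval of the ratio 32.6 to 49.1), SCD, which makes oleic acid, was 11.6-fold higher at E4, and SREBF1, a regulator of lipid synthesis, 3.66-fold. AGPAT3, ACSL1 and ELOVL1 were 3.03-fold, 2.39-fold and 1.88-fold higher at E7. The median of the fatty acid and triglyceride synthesis list was -1.15 (percentile 0, with 6 higher, 9 lower and 1 between, of 16), with -1.13 in cluster 2 and -0.14 in cluster 5. Fatty acid oxidation genes were higher at E7, among them HADH (2.28-fold), PPARA, a regulator of lipid breakdown (2.18-fold), and CPT1A, the carrier of fatty acids into mitochondria (1.88-fold). That list had a median of 0.77 (percentile 100, with 11 higher, 1 lower and 4 between, of 16), with 1.19 in cluster 2 and 0.69 in cluster 5. For fatty acid binding and lipid droplets the median was 0.46 (percentile 99.7, with 6 higher, 3 lower and 4 between, of 13), with 0.58 in cluster 2 and 0.82 in cluster 5, CIDEA, a lipid droplet protein, was 3.99-fold higher at E7, LPL 1.92-fold, and PLIN2, a lipid droplet coat, was at 1062 and 1464 CPM. FABP7 and DBI were 2.43-fold and 1.55-fold higher at E7. FABP7 turned to -0.38 in the clustering made without the deposited numbers.

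Lysosomal genes were higher at E7. NPC2, which carries cholesterol out of the lysosome, was 6.68-fold higher at E7 (1044 against 6973 CPM, interval of the ratio 6.49 to 6.88), and PSAP, an activator of lipid breakdown, was 3.97-fold higher at E7 (538 against 2137 CPM, interval of the ratio 3.81 to 4.13). LAMP1, CTSB and CTSV were 2.80-fold, 2.73-fold and 1.83-fold higher. Of the list, 11 of 20 measured members were at least 1.5-fold higher at E7, 1 at least 1.5-fold lower and 8 between, with a median of 0.68 (0.57 to 0.78), percentile 100, 0.62 in cluster 2 and 0.68 in cluster 5, and 0.48 in the mesenchymal-like cells (0.59 in their cluster 4 alone). The endocytic machinery list had a median of 0.20 (percentile 92.9), 0.23 in cluster 2 (percentile 95.8) and 0.35 in cluster 5 (percentile 99.7), with 14 of 17 members between the bounds. CLTA, a clathrin light chain, was 2.42-fold and AP2M1 1.71-fold higher at E7, EHD4 was 3.24-fold higher at E4, and EPN2 and VPS35 were at 392 and 451 CPM and 67.3 and 101 CPM. CTSV turned to -0.11 when each library was clustered alone and to -0.88 in the joint clustering made without the deposited numbers.

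Genes that handle vitamins, metals and foreign compounds were mostly higher at E7. STRA6, the retinol uptake receptor, was 2.56-fold higher, the iron transporters SLC11A2 and SLC40A1 2.73-fold and 2.65-fold, FTH1, an iron store, 1.67-fold, and MT4 1.78-fold (on the log2 scale -0.78 in cluster 5 alone), while TFRC, the transferrin receptor, was 5.92-fold higher at E4. The vitamin and metal handling median was 0.74 (percentile 100, with 8 higher, 2 lower and 2 between, of 12), with 1.27 in cluster 2 and 0.47 in cluster 5. GSTA3 and ALDH1A1 of the bile acid and xenobiotic metabolism list were 2.95-fold and 2.28-fold higher at E7, and that list had a median of 1.31 (percentile 100, with 8 higher, 4 lower and 0 between, of 12), with 1.72 in cluster 2 and 1.19 in cluster 5. In sterol esterification and efflux, ABCG2, an exporter, was 4.74-fold higher at E7, OSBPL8 1.52-fold, NR1H3 stood at 37.3 and 52.2 CPM and STARD4, a sterol carrier, was 6.05-fold higher at E4. The median of that list, 0.47 (percentile 97.3, with 2 higher, 3 lower and 2 between, of 7), had the opposite sign under 5 other settings, among them -0.11 in cluster 2 and -0.015 in cluster 5 and -0.29 with per-cell means.

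**Figure D3:**
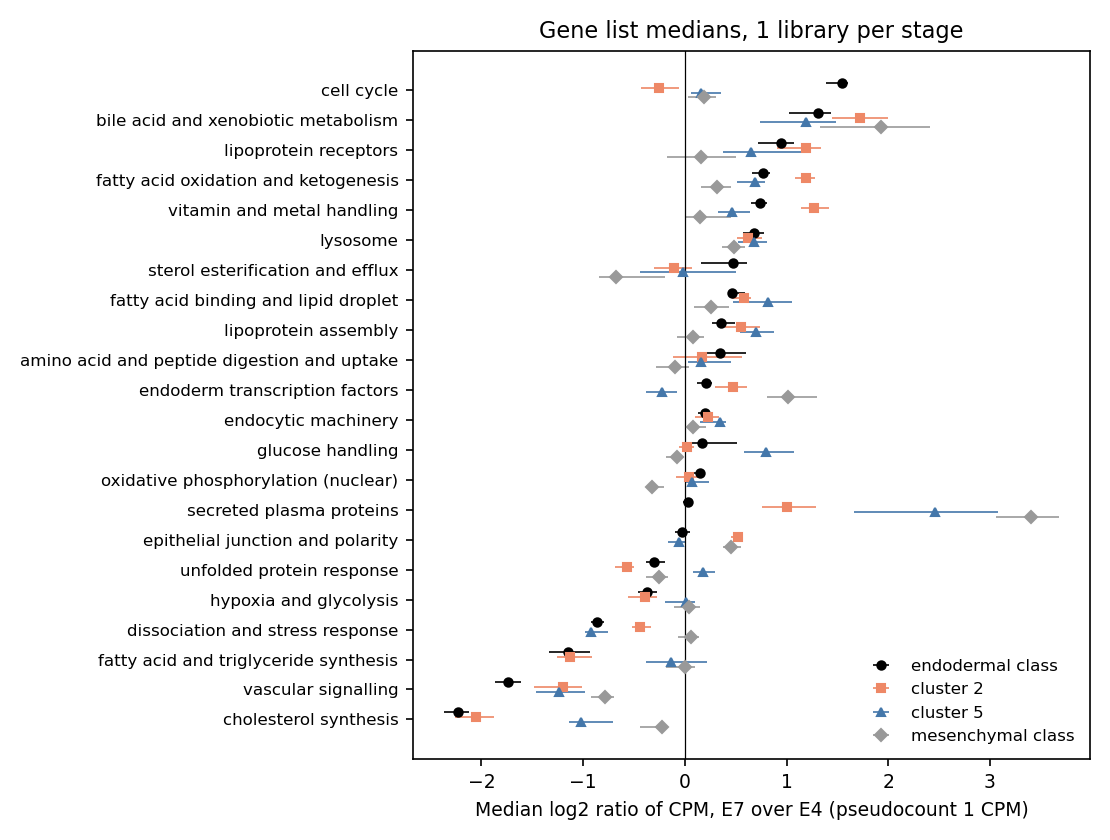
Median log2 ratio of CPM at E7 over E4 for each gene list (x axis) in the endodermal class, in clusters 2 and 5 alone and in the mesenchymal class, 1 library per stage; bars are 95% counting intervals. Cholesterol synthesis lies at -2.23 in the endodermal class and -0.23 in the mesenchymal class.

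Of the genes that met the size rule, IFI6 had the largest ratio toward E7. IFI6, which interferon induces, was 49.0-fold higher at E7 (41.7 against 2046 CPM, interval of the ratio 42.5 to 56.9), and RSAD2, an antiviral enzyme, was 19.0-fold higher at E7 (3.11 against 59.1 CPM, interval of the ratio 11.3 to 34.8). AFP, the fetal plasma protein, was 21.9-fold higher at E7 (17.8 against 388 CPM, interval of the ratio 17.6 to 27.6). SULT1C3, a sulfotransferase, and GSTA2, a glutathione transferase, were 13.96-fold and 7.26-fold higher at E7. IFI6 at E7 was at 7209 CPM in cluster 2 and 305 in cluster 3, against 174 CPM in mesenchymal-like and 294 in erythroid-like cells, where AFP stood at 16.5 and 110.5. LGALS1B (8.78-fold), N4BP2L1 (7.86-fold), PALMD (7.14-fold), TNFAIP8L3 (7.28-fold) and EXFABP, a lipocalin (6.79-fold), followed with NPC2.

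The 12 genes with the largest ratios toward E4 all stood higher in cluster 2 than in cluster 5 at E4. ACTC1, cardiac actin, was 291-fold higher at E4 (151 against 0.518 CPM, interval of the ratio 207 to 421), with 155 CPM in the E4 mesenchymal-like cells. NES, an intermediate filament gene, was 165-fold, ANGPTL2 173-fold, PODXL 174-fold, ID4 155-fold and CFC1 597-fold higher at E4. The smooth muscle genes TAGLN and ACTA2 were 57.6-fold and 53.0-fold higher, and MDK, a growth factor, 39.1-fold. GCG, which encodes glucagon, was 178-fold higher at E4 (198 against 1.11 CPM, interval of the ratio 141 to 229), with 286 CPM in cluster 2 and 2.14 in cluster 5. Its log2 ratio was 0.15 in cluster 5 alone and 0.055 without the 5% of cells with the highest doublet scores. VIPR2 and VSIG1, 71.0-fold and 68.8-fold higher at E4, turned to 1.19 and 0.83 in the clustering made without the deposited numbers.

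Cell cycle genes were higher at E7 in the class as a whole, but lay near or below 0 in clusters 2 and 5, the clusters named in the class at both stages. RRM2, needed to make deoxynucleotides, was 5.57-fold, BUB1 4.02-fold, MCM6 3.58-fold, BIRC5 3.20-fold, CDK1 2.71-fold and PCNA 2.04-fold higher. The list median was 1.54 (percentile 100, with 21 higher, 1 lower and 2 between, of 24), with -0.25 in cluster 2 and 0.16 in cluster 5. CDK1 turned to -0.10 in cluster 5 alone, and in cluster 2 alone RRM2, PCNA and MCM6 turned to -0.50, -0.57 and -0.16. The class at E7 also holds clusters 1, 3 and 10, whose 292, 95 and 123 E4 cells stayed unnamed and were left out. Cluster 3 had the cell cycle gene KIF11 among its leading genes at E7. Its E4 cells had CENPF among their leading symbols, but behind WT1, HOXA13, TFAP2B, SOX10, OSR1 and PAX2. Whether the E4 and E7 cells of cluster 3 are of the same kind was not tested. The class ratio thus sets E7 cells of clusters 1, 3 and 10 against an E4 side without cells of these clusters.

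Vascular signalling and stress genes were lower at E7. At E4 the vascular list was lower in the endodermal than in the endothelial-like (median -1.59) and mesenchymal-like cells (-1.06), so RNA of those cells may add to its E4 level. FLT4, a receptor of lymphatic growth factors, was 21.1-fold, NR2F2 11.0-fold, EFNB2 9.32-fold, PDGFB 8.88-fold, PDGFA 1.57-fold and BMP4 1.56-fold higher at E4, and the list median was -1.74 (percentile 0, with 1 higher, 15 lower and 2 between, of 18), with -1.19 in cluster 2 and -1.23 in cluster 5. The heat shock genes HSPB1 and HSPA2 were 4.29-fold and 2.80-fold higher at E4, DUSP1 2.99-fold, KLF2 2.14-fold and KLF6 1.55-fold, while HSP90AA1 was 1.79-fold higher at E7. KLF2 lay at 0.0081 in the clustering made without the deposited numbers. The dissociation and stress response median was -0.86 (percentile 0, with 1 higher, 13 lower and 5 between, of 19), with -0.44 in cluster 2 and -0.92 in cluster 5, 0.057 in the mesenchymal-like cells and -0.26 in their cluster 4 alone. HERPUD1 of the unfolded protein response was 2.10-fold higher at E4, ATF4, HSP90B1 and CANX stood at 606 and 419.8 CPM, 542 and 394 CPM and 545 and 744 CPM, and the median was -0.31 (percentile 2.19, with 0 higher, 1 lower and 14 between, of 15), with -0.57 in cluster 2 and 0.18 in cluster 5. PFKFB3, P4HA2 and GAPDH of the hypoxia and glycolysis list were 4.26-fold, 2.93-fold and 1.91-fold higher at E4. LDHA, also in this list and given below with glucose handling, was higher at E7. ENO1 stood at 1318 and 1372 CPM, and the median of the hypoxia and glycolysis list was -0.37 (percentile 1.22, with 1 higher, 6 lower and 9 between, of 16), with -0.39 in cluster 2 and 0.0076 in cluster 5. In the clustering made without the deposited numbers, both of these medians were above 0, at 0.068 and 0.21.

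Plasma protein genes split in the class as a whole, but were mostly higher at E7 in clusters 2 and 5 alone. In cluster 2, 8 of 14 measured members were higher and 2 lower, at percentile 100. In cluster 5, 7 of 9 were higher and 1 lower, also at percentile 100. Cluster 2 held 246 of 393 class cells at E4 and 1648 of 6558 at E7, so the class median also depends on the mix of clusters. TTR, a carrier of thyroid hormone, was 1.77-fold higher at E7, TF, the iron carrier, was at 842 and 861 CPM, and the fibrinogen genes FGB and FGG were 2.59-fold and 2.69-fold higher at E4. The secreted plasma proteins median was 0.032 (percentile 71.2, with 6 higher, 6 lower and 1 between, of 13), against -0.17 with per-cell means, and 1.01 in cluster 2 and 2.46 in cluster 5, and FGB and FGG turned to 2.46 and 0.91 in cluster 5 and to 5.82 and 5.27 in the clustering made without the deposited numbers. TTR in cells of other classes at E7 stood at 452 CPM (mesenchymal-like) and 628 (erythroid-like). Glucose handling had a median of 0.17 (percentile 89.8, with 6 higher, 4 lower and 5 between, of 15), with 0.021 in cluster 2 and 0.80 in cluster 5, and FBP1 was 4.77-fold, LDHA 3.59-fold and LDHB 1.86-fold higher at E7 (LDHB -0.11 in cluster 2 alone), with PKLR at 822 and 804 CPM. Amino acid and peptide digestion and uptake had a median of 0.34 (percentile 97.3, with 5 higher, 1 lower and 4 between, of 10), with 0.16 in cluster 2 and 0.16 in cluster 5. The peptidase DPP4 was 3.15-fold and the carrier SLC7A5 2.88-fold higher at E7, SLC6A14 was 27.6-fold higher at E4, and SLC7A1 and SLC38A2 stood at 58.8 and 55.0 CPM and 199 and 208 CPM.

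Junction genes of the epithelium had a class median near 0 and a higher one in cluster 2. EPCAM, an epithelial adhesion gene, stood at 3393 and 2857 CPM, CLDN1 at 2468 and 2299 CPM, and CDH1, E-cadherin, was 1.79-fold higher at E4, although it turned to 0.60 in cluster 2 alone. LAMA1 was 2.02-fold higher at E7, the collagen genes COL4A1 and COL4A2 were 3.36-fold and 1.89-fold higher at E4, and the epithelial junction and polarity median was -0.026 (percentile 40.4, with 3 higher, 4 lower and 12 between, of 19), with 0.52 in cluster 2 and -0.057 in cluster 5 and 0.13 with TMM scaling. Among endoderm transcription factors, HNF4A was 5.27-fold, NR5A2 2.93-fold and GATA4 1.51-fold higher at E7, HHEX was 4.55-fold higher at E4, and KLF5 and GATA6 stood at 466 and 375 CPM and 384 and 393 CPM. That list had a median of 0.21 (percentile 94.8, with 5 higher, 4 lower and 7 between, of 16), with 0.48 in cluster 2 and -0.22 in cluster 5. HHEX, COL4A1 and COL4A2 turned to 0.19, 0.12 and 0.63 in the clustering made without the deposited numbers. The nuclear genes of oxidative phosphorylation had a median of 0.15 (percentile 86.9, with 1 higher, 0 lower and 16 between, of 17), with 0.041 in cluster 2 and 0.072 in cluster 5. NDUFB5 was 1.62-fold higher at E7, with NDUFA1, NDUFA4, SDHA, COX6A1 and COX6C at 56.6 and 37.7 CPM, 373 and 251 CPM, 61.7 and 90.5 CPM, 533 and 419.7 CPM and 373 and 449.9 CPM.

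Globin genes, which epithelial cells should lack, were detected in the class, at E7 far below the erythroid-like cells. The level of HBE in the class at E7 still lay above the class levels of APOC3, SCARB1 and APOB given above. HBE and HBZ stood at 4.66 and 136 CPM and 31.5 and 90.8 CPM, HBAD and HBA1 at 7.10 and 46.7 CPM and 8.44 and 40.5 CPM, against 55186 CPM of HBE in the E7 erythroid-like cells. The primitive globin list had a median of 3.05 and the adult-type globin list 2.35, from 2 measured members each, and HBAD turned to -0.91 after free RNA was subtracted. Over all lists together, 331 genes were measured, of which 116 were at least 1.5-fold higher at E7, 92 at least 1.5-fold lower and 123 between. The median log2 ratio of all measured genes with a symbol was -0.027. It was 0.13 with TMM scaling, 0.13 in the clustering made without the deposited numbers and -0.12 in cluster 2 alone, and values under those settings are relative to these shifts.

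The mesenchymal-like cells served as the only other class with at least 100 cells in both libraries, with clusters 0, 4, 7 and 13 at E4 and cluster 4 at E7 (4902 and 165 cells). Clusters 0 and 7 held only 13 and 2 cells at E7, and whether their E4 cells come from the embryo body was not tested. MGP, an inhibitor of calcification in connective tissue, was 27.0-fold higher at E7 (14.1 against 382 CPM, interval of the ratio 24.4 to 29.9), and 12.03-fold (10.8 to 13.5) in cluster 4 alone, the only mesenchymal-like cluster at both stages. CSRP3 and ANKRD1, both known from striated muscle, were 69.4-fold (counting interval 23.7 to 337) and 76.0-fold (21.0 to 628) higher at E4, from 3 and 2 counts at E7, and 35.6-fold (12.2 to 173) and 67.4-fold (18.6 to 557) in cluster 4 alone. ACTC1 was 43.9-fold (73.8-fold in cluster 4 alone), HAPLN1, a matrix linker, 20.3-fold and CRABP1, which binds retinoic acid, 19.4-fold higher at E4, of which HAPLN1 and CRABP1 were not among the 12 genes named toward E4 in cluster 4 alone. IFI6, TTR, PLA2G2A and RBP4A were 944-fold, 38.8-fold, 46.0-fold and 33.8-fold higher at E7, and 411-fold, 24.1-fold, 47.0-fold and 32.1-fold in cluster 4 alone. For IFI6 and TTR the E7 levels of 174 and 452 CPM lay below the 294 and 628 CPM of the erythroid-like cells. PLA2G2A was among the leading genes of E7 cluster 1, an endodermal epithelial-like cluster, and no level in other classes is given here for PLA2G2A and RBP4A. Endodermal epithelial-like cells were 95.3% of the E7 library, so RNA from them may add to these E7 levels. The medians were 0.079 for lipoprotein assembly, 0.16 for receptors, 0.32 for fatty acid oxidation, -0.78 for vascular signalling and 3.40 for secreted plasma proteins, the last over 4 measured genes. In cluster 4 alone they were 0.30, 0.57, 0.23, -0.31 and 3.81. The plasma protein genes include TTR, so the same limit holds for them. Endoderm transcription factors and epithelial junction and polarity also had medians above 0 in the mesenchymal-like cells, at 1.01 and 0.45. Differences between the classes were not tested.

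Within each stage, the endodermal epithelial-like cells stood apart from the mesenchymal-like cells by plasma protein and endoderm transcription factor genes, among other lists. The median log2 ratio of endodermal over mesenchymal-like cells was 4.23 at E4 and 3.29 at E7 for secreted plasma proteins, and 3.78 and 3.20 for endoderm transcription factors. Bile acid and xenobiotic metabolism gave 3.26 and 2.80, and epithelial junction and polarity 1.34 and 2.36. Lipoprotein receptors gave 0.50 (percentile 83.4) and 1.22 (percentile 98.3), and lipoprotein assembly -0.064 and 0.14. Lysosomal genes gave 0.59 and 0.66, and cholesterol synthesis -0.21 and -2.27. The macrophage-like cells of E4 exceeded the endodermal cells in lysosomal genes, with a median of -1.90 for endodermal over macrophage-like cells. Some list genes are also markers that named the classes and how the deposited clusters were made was not given, so these values describe the clusters and are not independent of them.

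Sub-clusters of the endodermal epithelial-like cells seldom mixed the stages. Of 10 sub-clusters, sub-cluster 0 held 265 of the 393 E4 cells and 3 E7 cells. The most mixed, sub-cluster 3, held 71 E4 and 557 E7 cells. In sub-cluster 8, with 7 E4 and 365 E7 cells, lipoprotein assembly genes had a median log2 ratio of 1.05 over the rest of the class and lipoprotein receptors 0.62. Sub-cluster 9 (3 and 624 cells) gave -1.18 and -1.33 for the same lists, with cell cycle genes at 0.74. Cholesterol synthesis genes had a median of 2.54 in sub-cluster 0. A sub-cluster mostly of 1 library may be that library and not a cell type.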

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

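The tests of the tissue lists were chosen only after the leading genes of these clusters had been seen.

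Clusters 8, 12, 14 and 16 held 15.9% of the E4 cells, lie outside every comparison and are led by genes of neural tissue, heart muscle, pharyngeal tissue and the nephric duct. Of 42 further measured genes of these tissues, without the genes of the exclusion rule, 73.8% were at least 3-fold higher in their cluster than in the rest of the E4 library, with 9 of 12 neural, 13 of 17 heart muscle, 4 of 6 pharyngeal and 5 of 7 nephric genes, which argues against a few leading genes without a wider programme. MYH15, a heart myosin gene, stood at 2515 against 93.4 CPM and NCAM1, a neural adhesion gene, at 271 against 60.8 CPM, while 11 of the genes also reached 10 CPM in the E7 library and 3 stand in another list used here. Tissue of the embryo body in the E4 suspension may be the source, a hypothesis found and tested on the same data. The exclusion covered only the tissues named here. The mesenchymal-like E4 clusters 0 and 7 (2428 and 694 cells) stayed in the comparisons, and their origin was not tested. HAPLN1 and COL2A1 were among the leading symbols of cluster 0, and HOX genes such as HOXC10 and HOXA13 among those of cluster 7. The labels name only the yolk sac membrane and no sort, and a biological difference between E4 and E7 stays open and untested.

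Cells in no named class made up 27.5% of the E4 library and 0.494% of the E7 library. Features without a symbol held 26.7% of the UMIs at E4 and 28.2% at E7, and were used in no gene comparison. Both lie outside the comparisons, which is what drew attention to them.

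For 3 lists the medians in the endodermal and mesenchymal-like cells lay on opposite sides of 0 and the counting interval of each excluded 0, a difference that was not tested. Sterol esterification and efflux genes had medians of 0.47 and -0.67, nuclear oxidative phosphorylation genes 0.15 and -0.33, and glucose handling genes 0.17 and -0.080, in that order, and in cluster 4, the only mesenchymal-like cluster at both stages, the medians were -0.25 (-0.47 to -0.0036), -0.30 and -0.097. The endodermal value for sterol esterification and efflux took the sign of the mesenchymal-like cells in cluster 2 (-0.11) and cluster 5 (-0.015), after free RNA subtraction (-0.23), with per-cell means (-0.29) and after thinning (-0.25), and that for oxidative phosphorylation in the own joint clustering (-0.053).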

How the results depend on the processing

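The settings chosen after the data were seen are cluster 2 alone, cluster 5 alone, the own joint clustering, cells with more than 2500 genes, cells without the highest doublet scores, the first naming rule and the missing embryo-tissue exclusion. No paired analysis was possible because each stage has 1 library, so they share only replicate number 1, and no result comes from a test. Removing called doublets was not run, since the caller marked too few cells for its calls to be used, and no cell has fewer than 1000 UMIs. The medians of lipoprotein assembly and lipoprotein receptors were above 0 and that of cholesterol synthesis below 0 under every setting in which list medians were computed. Only shares of cells were computed at Leiden resolutions 0.5 and 2 and with list genes allowed for clustering. The same holds for the first naming rule and the missing embryo-tissue exclusion. The 2-fold bound and the 50 CPM minimum gave only counts of list members. Of 146 named genes, 14 had the opposite sign in the own joint clustering, 5 in cluster 2 alone and 5 in cluster 5 alone, and none with TMM scaling, with per-cell means or without ribosomal and globin genes. With TMM scaling 19 of 24 list medians moved beyond counting error, in the direction of the shift of all genes, and none did without ribosomal and globin genes. Sums of 393 E4 cells limit genes of low level most, and the cause of each difference listed here was not tested. Shares are in percent of a library and other values are log2 ratios or counts of genes.

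With a bound of 2-fold the value was 76 list members higher at E7. With 50 CPM as the minimum the value was 51 list members lower at E7. At Leiden resolution 0.5 the values were ectodermal epithelial-like E4 9.54%, erythroid-like E7 0.930%, mesenchymal-like E4 56.0% and unnamed E4 21.2%. At Leiden resolution 2 the values were ectodermal epithelial-like E4 6.47%, endodermal epithelial-like E7 86.1%, erythroid-like E4 0.752%, mesenchymal-like E4 55.4%, unnamed E4 23.7% and unnamed E7 9.11%. With TMM scaling the values were lipoprotein assembly 0.62 and lipoprotein receptors 1.09. In cluster 2 alone the values were cell cycle -0.25, lipoprotein assembly 0.55, lipoprotein receptors 1.19, sterol esterification and efflux -0.11, CDH1 0.60, LDHB -0.11, MCM6 -0.16, PCNA -0.57 and RRM2 -0.50. In cluster 5 alone the values were endoderm transcription factors -0.22, hypoxia and glycolysis 0.0076, lipoprotein assembly 0.70, lipoprotein receptors 0.65, sterol esterification and efflux -0.015, unfolded protein response 0.18, CDK1 -0.10, FGB 2.46, FGG 0.91, GCG 0.15 and MT4 -0.78. With each library clustered alone the values were endoderm transcription factors -0.27, lipoprotein receptors 0.48, CTSV -0.11, ectodermal epithelial-like E4 4.30%, endodermal epithelial-like E4 5.03%, macrophage-like E7 0.305%, mesenchymal-like E4 56.0% and unnamed E4 25.6%. Under the first naming rule the values were endodermal epithelial-like E4 2.72%, endodermal epithelial-like E7 23.9%, erythroid-like E7 72.8% and unnamed E4 25.9%. After free RNA was subtracted the values were sterol esterification and efflux -0.23 and HBAD -0.91. With list genes allowed for clustering the values were ectodermal epithelial-like E4 6.68%, endodermal epithelial-like E4 2.003%, endodermal epithelial-like E7 89.7%, erythroid-like E4 0.752%, erythroid-like E7 0.901%, mesenchymal-like E4 52.6%, unnamed E4 28.7% and unnamed E7 6.10%. With per-cell means the value was sterol esterification and efflux -0.29. In cells with more than 2500 genes the values were endodermal epithelial-like E7 96.1% and erythroid-like E7 0.774%. Without a CPM minimum the values were lipoprotein assembly 0.66 and lipoprotein receptors 0.49. Without the embryo-tissue exclusion the values were endodermal epithelial-like E4 5.27%, mesenchymal-like E4 59.2% and unnamed E4 21.6%. In the own joint clustering the values were hypoxia and glycolysis 0.21, lipoprotein assembly 0.86, lipoprotein receptors 0.43, oxidative phosphorylation (nuclear) -0.053, unfolded protein response 0.068, APOH 1.83, COL4A1 0.12, COL4A2 0.63, CTSV -0.88, FABP7 -0.38, FGB 5.82, FGG 5.27, GCG 0.099, HHEX 0.19, KLF2 0.0081, MT4 -0.57, SORL1 -0.41, VIPR2 1.19, VSIG1 0.83, ectodermal epithelial-like E4 6.46%, endodermal epithelial-like E4 1.66%, endodermal epithelial-like E7 87.2%, erythroid-like E7 0.944%, mesenchymal-like E4 55.7% and unnamed E7 8.66%. With cells thinned to 1 depth the value was sterol esterification and efflux -0.25. Without the highest doublet scores the value was GCG 0.055.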

Other observations

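The test with cluster 5 alone was chosen only after the result was seen, the tests by thinning, by free RNA and of cluster 10 before. Cluster 9 carried globin genes at both stages in different proportions. HBZ stood at 8108 CPM and HBE at 3416 CPM in its E4 cells, against 25069 and 55186 CPM in its E7 cells. HBA1 stood at 2797 and 13226 CPM and HBAD at 1820.4 and 18819.9 CPM. Pou5f3, a pluripotency factor gene singled out after its values were seen, was at 178 CPM in cluster 1 and 178 in cluster 5 at E4 and at 71.2 and 35.5 at E7, against 4.96 and 5.90 in mesenchymal-like cells.

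The higher median of the lipoprotein assembly genes at E7 may have technical sources. If gut endoderm of the embryo among the E4 cells of cluster 2 were the whole cause, the median in cluster 5 alone should be at or below 0. It was 0.70 (0.54 to 0.88), so the higher median does not need the E4 cells of cluster 2. What the E4 cells of cluster 5 are is itself open. They raised 5 of 16 endodermal markers, had Pou5f3 and VENTX among their leading symbols and spread over 12 clusters when clustered anew. Any E4 cells low in these genes would give a median above 0. The value therefore cannot decide whether tissue of the embryo makes up the E4 side, and gut endoderm within cluster 5 was not tested. Thinning to 3800 UMIs per cell left out 0 E4 and 656 E7 cells and gave 0.37 (0.25 to 0.62), above the bound of 0 set in advance. Random thinning keeps the expected share of each gene within a cell, so it could hardly have moved the median to 0. It cannot decide whether a difference in UMIs per cell contributes. After subtraction of free RNA the median was 0.38 (0.29 to 0.48), above the bound of 0 set in advance, but the subtraction took only 1.05% of the E7 counts, under a limit of 5% set after this value was seen, and its profile came from the other cells. Free RNA from the endodermal cells themselves therefore stays open, as does the difference in stage, which the design confounds with the library.

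Cluster 10 had a median of 7907 UMIs per cell at E4 and 4970.5 at E7, against 12361 and 9715 in the other cells. Ribosomal protein genes took 0.487 times the share they took in the rest of the E4 library and 0.402 times at E7, both under the bound of 0.5 set in advance, at E4 narrowly. Nuclei or leaky cells with little cytoplasmic RNA may make up this cluster. Features without a symbol held 35.2% and 45.8% of its UMIs, against 26.6% and 27.5% elsewhere, and no biological explanation was tested.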
